A study of Mus musculus with 24 samples.

How the data were processed

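Messenger RNA of mouse spermatids was measured on Illumina bead arrays with biotin-labelled cRNA. The labels give 2 stages of sperm formation, round and condensing spermatids, and 2 genotypes, wild type and a knockdown of both CBP and p300 in cells after meiosis, all at an age of 7 weeks. Each of the 4 groups holds 6 arrays, 24 in all. The labels do not say whether replicates are separate animals, so the p-values measure the spread between these samples alone. If arrays that follow one another in number share an animal or a pool, a group holds fewer than 6 independent samples and the errors given for 6 are too small.

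The deposited table of non-normalized values gives, per the file headers, the mean bead intensity of each of 45281 probes on a linear scale for every array. The same table gives, per the file headers, a detection p-value per probe and array, which ranks a probe's signal against negative control beads. The authors also deposited a second table of intensity values on a linear scale. Its values show quantile normalization across all 24 arrays and keep the ranks of each array in the first table. The software, background handling and statistical test used by the authors are not given in the sources used here.

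All fits started from the non-normalized intensities. Background was corrected by the normexp method with its noise level inferred from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale, as in the neqc procedure of limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.05 in at least 6 arrays were kept, which left 19086 probes. Of these, 3143 had no gene symbol and 10 had several, and both kinds were left out of the gene counts. For each gene symbol the probe with the highest mean log2 value was used, giving 10759 genes. Gene symbols came with the probe annotation supplied for the arrays, and 99.8% of them were found in a RefSeq gene table. No genome build is named, so no positions are given.

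The limma model held 4 group means, with 1 pooled spread per gene moderated across genes, and 5 contrasts: knockdown against wild type in round and in condensing spermatids, condensing against round spermatids in wild type and in the knockdown, and the difference between both knockdown effects. Tests were two-sided moderated tests of limma, with Benjamini-Hochberg adjustment over all 10759 genes within a contrast, and a gene counts as called at an adjusted p under 0.05. Errors given with log2 differences are standard errors of the model, and errors given with group levels are standard deviations over 6 arrays. The number of arrays limits the precision: the median 95% interval reached 0.29 log2 (1.22-fold) to either side for a contrast of 2 groups and 0.41 log2 (1.33-fold) for the difference between the knockdown effects.

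Gene lists fixed before the data were examined were tested with camera of limma at a preset correlation of 0.01 between genes and again with an estimated correlation, each adjusted over 28 lists within a contrast. The 29 lists were the targeted genes, glycolysis, glucose and lactate transport, pyruvate dehydrogenase and citric acid cycle, oxidative phosphorylation, fatty acid oxidation, cholesterol and isoprenoid synthesis, fatty acid and glycerolipid synthesis, antioxidant and thioredoxin system, autophagy, vesicle trafficking and Golgi, acrosome, flagellum, spermatid chromatin packaging, haploid transcription programme, sex-linked multicopy spermatid genes, acetylation writers, readers and erasers, ribosomal proteins, proteasome, stress and immediate early genes, and markers of pachytene and meiotic spermatocytes, spermatogonia, Sertoli cells, Leydig cells, macrophages and leukocytes, peritubular and stromal cells, endothelium, erythroid cells and epididymal epithelium. A list needed 3 measured members, so the targeted genes were not tested as a list. Members past the threshold were also counted with p-values adjusted over the list alone. The fry test of limma was run beside camera: its directional p asks whether a list's genes move, on balance, in 1 direction, its mixed p whether they change in either direction, and neither compares the list with other genes.

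The rule for the genes named in the text was fixed before the data were examined. In both knockdown contrasts and the wild-type stage contrast it takes Crebbp and Ep300, the 4 largest called rises and 4 largest called falls whose probe was detected in all 6 arrays of a group, and the 2 called members with the smallest adjusted p from each of up to 8 lists with 3 or more called members. It adds Tnp1, Tnp2, Prm1, Prm2 and Brdt, and in the knockdown contrasts the brightest member of each marker list of another cell type. For the difference between the knockdown effects it takes the 4 largest called values in each direction, and where nothing is called, the 3 genes with the smallest p as values. Symbols that name only a clone, locus or gene model stay in the counts and are not named. Genes named outside the rule are marked in the text as chosen after their values were seen.

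The procedure was tested on simulated data of the same size, in which 200 of 10759 genes were shifted in 10 runs. The shifts were added to normalized log2 values of genes past the detection filter. The shares below therefore do not hold for changes of RNA near background, whose measured folds are smaller. Shifts of 2-fold were recovered for 96.7% of genes in the round and 95.9% in the condensing knockdown contrast, shifts of 1.5-fold for 54.4% and 51.9%, and 3.31% and 4.88% of calls were false. For the difference between the knockdown effects the shares were 74.1% and 20.9%, with 10.3% of calls false. With no simulated effect, the highest number of calls in a run was 3, for that difference. These 10 runs do not bound the calls that regrouped real arrays can give. Of the 100 splits described below, 16 other than the real one gave a call in the round contrast (up to 2608). For the difference between the knockdown effects 4 did (up to 1114). In 20 runs with no list effect, camera called at least 1 of 28 lists in 6 runs with the preset correlation and in 0 with the estimated correlation, and a list shifted by 0.5 log2 was called in all 20 with both.

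Alternatives were the authors' normalized values, no background correction, median scaling, quantiles within each cell type, no or a stricter detection filter (p under 0.01), only the arrays of a contrast, all detected probes, the mean of a gene's probes, a variance trend with robust moderation, array weights, an adjusted p under 0.01, a fold change of at least 1.5, and each array left out in turn. The omission of 3 round spermatid arrays together, a covariate for variation within groups, and 3 treatments of consecutive arrays of a group (pairs as a random block by duplicateCorrelation of limma, pairs averaged, and the position of the pair as a fixed block within a stage) were added after the data were seen. The error of a correlation across genes is a jackknife over arrays. Counts were set beside those of 100 splits of the same arrays, drawn with a fixed seed and including the real split, and beside those of splits that keep consecutive arrays together (10, or 100 drawn for the difference between the knockdown effects). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.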

Results

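The arrays compared mouse spermatids at 2 stages, in wild type and in a combined knockdown of CBP and p300. Round spermatids are haploid cells that still package their DNA with histones, and condensing spermatids are the later cells in which transition proteins and protamines take over. CBP and p300, encoded by Crebbp and Ep300, are histone acetyltransferases that act as transcriptional coactivators. The series concerns the part of the late spermatid programme, metabolism included, that needs these enzymes. Each group held 6 arrays, and 15687 to 18411 of 45281 probes (34.6% to 40.7%) were above background on an array. Stage separated the arrays most: the main axis of variation carried 71.5% of the variance and parted round from condensing samples. Log2 values correlated at 0.904 to 0.955 between stages, and at 0.969 to 0.995 between genotypes within a stage.

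Crebbp and Ep300 themselves did not differ detectably between the genotypes. Crebbp (probe ILMN_1255457) stood at 7.32 ± 0.22 log2 (SD, n = 6) in wild-type and 7.34 ± 0.38 in knockdown round spermatids, and at 5.82 ± 0.21 and 5.71 ± 0.41 in condensing spermatids. Ep300 (probe ILMN_2800358) stood at 7.93 ± 0.38 and 7.97 ± 0.39 in round, and at 6.59 ± 0.28 and 6.57 ± 0.14 in condensing spermatids. The 95% intervals put the knockdown level of Crebbp at 79.1% to 129% of wild type in round and 72.5% to 118% in condensing spermatids, and that of Ep300 at 81.3% to 132% and 77.4% to 125%. A second Crebbp probe, detected on 22 arrays, gave a difference of -0.45 in condensing spermatids with an adjusted p of 0.471, and a second Ep300 probe, detected on 10 arrays, gave 0.19 in both stages. So the main probes showed no loss of transcript beyond these intervals. Whether the knockdown lowers the part of the transcripts that these probes measure is not known. The values therefore do not settle whether the genotype labels are right. Both genes fell from round to condensing wild-type spermatids, Crebbp 2.83-fold (log2 SE 0.17, n = 6 per group, limma adjusted p = 1.37e-08) and Ep300 2.53-fold (log2 SE 0.17, adjusted p = 8.94e-08), with no overlap between the stages. Over 25 other settings the log2 change ran from -1.57 to -0.71 for Crebbp and from -1.40 to -0.79 for Ep300. The second probes gave -1.38 for Crebbp and -0.57 for Ep300, so the folds are not exact.

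**Figure D1:**
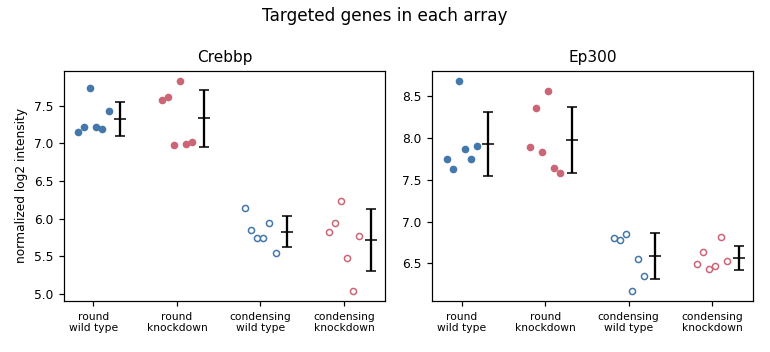
Normalized log2 intensity of Crebbp and Ep300 on each of the 24 arrays. Points are arrays (filled, round; open, condensing; blue, wild type; red, knockdown), bars are the mean ± SD of 6 arrays, and the genotypes overlap within each stage.

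The stage change in wild type asks how the transcript pool changes as spermatids condense. The largest rises were genes of other cell types. Hba-a1, an alpha globin, rose by 6.48 ± 0.31 log2 (89.5-fold; SE, n = 6 per group) and the beta globins Hbb-bt and Hbb-bs by 6.26 ± 0.29 and 5.97 ± 0.30, values that near-identical globin genes can share on hybridization. These globins stood at 14.1, 14.1 and 14.3 log2 in wild-type condensing samples, near the highest value of 15.2 on every array, so their folds are not exact. Cst12, a cystatin from the Sertoli marker list, rose by 3.94 ± 0.19 (15.3-fold). Alas2, the erythroid enzyme of heme synthesis, rose by 3.72 ± 0.12, Cldn11, a tight junction protein of Sertoli cells, by 3.43 ± 0.12, and Rhox5, a Sertoli cell homeobox gene, by 3.31 ± 0.12. The highest adjusted p among these rises was 9.01e-16, and the stages did not overlap in any of them. Over 25 other settings the rise ran from 1.96 to 3.95 for Alas2, 1.74 to 3.52 for Rhox5 and 2.82 to 3.61 for Cldn11, so its size depended on the processing. The largest named falls were Tshb (-2.42 ± 0.16, at least 3.94-fold lower because its probe was not detected in any wild-type condensing array), Cryba2 (-2.38 ± 0.13), Speer4e (-2.27 ± 0.19) and Xntrpc (-2.25 ± 0.15). Of the packaging genes, Tnp2, a transition protein, rose by 0.96 ± 0.15 (adjusted p = 3.16e-06). Tnp1 did not pass the test (-0.04, adjusted p = 0.748), nor did Brdt, a bromodomain protein of spermatids (-0.24 ± 0.12, adjusted p = 0.0877), for which another probe gave -0.95 (adjusted p = 6.39e-08). Prm1, a protamine, fell by 0.23 ± 0.10 (adjusted p = 0.0373, a call lost in 8 of 12 omissions of an array), but median scaling gave 0.61 for Prm1, 0.90 for Tnp1 and 0.14 for Brdt (adjusted p = 0.322), so the direction of these 3 genes depended on the scaling, and the Prm1 call was also lost with consecutive arrays as a random block (adjusted p = 0.0541). Prm2 was not analysed here. The limma test called 6903 of 10759 genes, 3262 higher and 3641 lower in condensing spermatids, of which 1163 and 794 changed at least 2-fold. Median scaling in place of quantiles moved the median of all genes from -0.03 to 0.30 and the share of calls that were rises from 47.3% to 66.8%.

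Markers of somatic and blood cells rose together from round to condensing wild-type samples. Of 14 measured Sertoli markers 13 rose and 0 fell (median 2.86; Cst12, Cldn11, Rhox5), by camera with an adjusted p of 1.41e-10, and an adjusted p = 0.0364 with an estimated correlation. Of 15 macrophage and leukocyte markers 13 rose and 0 fell (median 2.84-fold), among them Cd74, the invariant chain, by 2.86 and Fcer1g, an Fc receptor subunit, by 1.86 (camera adjusted p = 8.27e-06; adjusted p = 0.0661 with an estimated correlation). Of 6 erythroid markers 5 rose (median 4.84; adjusted p = 1.12e-04 and 0.0544 with an estimated correlation). Of 13 peritubular and stromal markers 10 rose and 1 fell (median 1.63; adjusted p = 2.82e-04 and 0.0544 with an estimated correlation), such as Myl9, a myosin light chain of smooth muscle, by 2.81 and Sparc, a matrix protein, by 2.55. Of 10 endothelial markers 8 rose (median 1.00; adjusted p = 0.00139 and 0.0544 with an estimated correlation), such as Egfl7 by 1.67 and Vwf, von Willebrand factor, by 1.46. Other probes also rose, by 0.43 and 0.97 for Egfl7, 0.94 and 2.19 for Sparc, and 1.59 and 3.03 for Cd74. Leydig cell markers (4 up and 1 down of 6; adjusted p = 0.0700) and epididymal epithelium markers (4 up and 1 down of 6; adjusted p = 0.140) were not called as lists. Spermatogonia markers (3 up and 1 down of 11; adjusted p = 0.636; median -0.00, mean 0.16) and meiotic spermatocyte markers (4 up and 11 down of 22, median -0.32; adjusted p = 0.143) were not called either. The medians of the Sertoli, leukocyte, erythroid, stromal and endothelial lists were above 0 under each of the scalings tried.

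**Figure D2:**
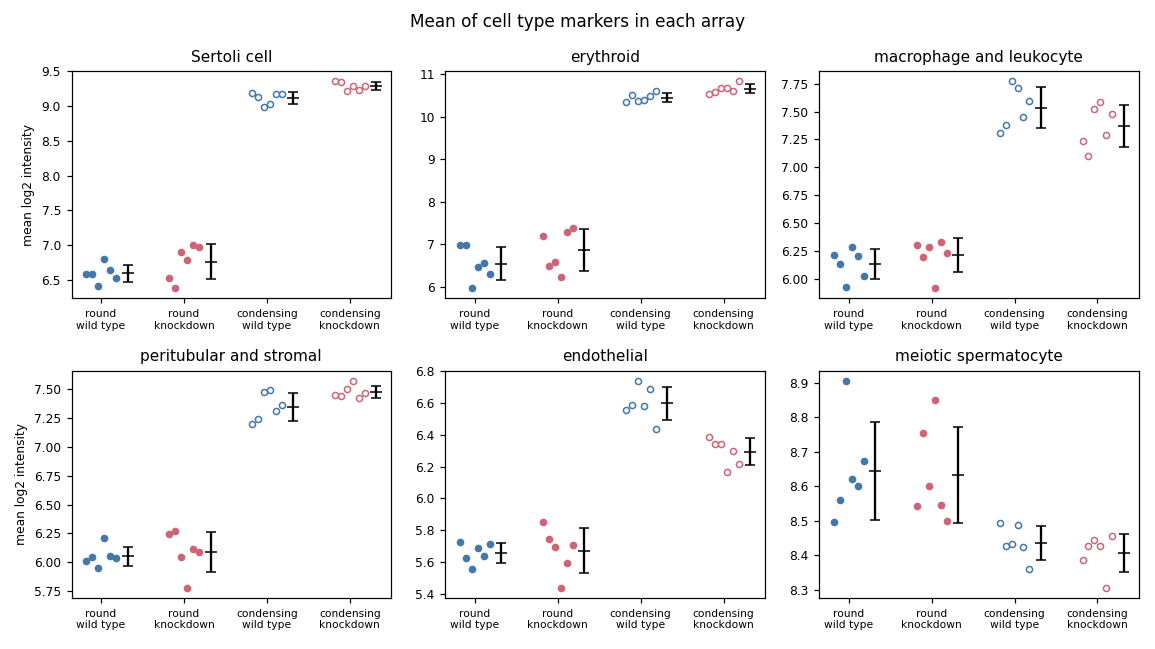
Mean normalized log2 intensity of marker lists on each array, by group. Points are arrays (filled, round; open, condensing; blue, wild type; red, knockdown), and bars are the mean ± SD of 6 arrays; markers of Sertoli, erythroid, leukocyte, stromal and endothelial cells lie higher in condensing than in round samples.

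Among germ cell programmes, genes of the acrosome and the flagellum lay lower in condensing wild-type samples. Of 31 acrosome genes 20 fell and 6 rose (median -0.66), with Zpbp, a zona pellucida binding protein, at -1.32 ± 0.12 and Acr, the protease acrosin, at -1.17 ± 0.10, and with Prss37 up by 1.69 ± 0.15. Of 45 flagellum genes 27 fell and 10 rose (median -0.55), such as Spag6, an axoneme protein, at -1.49 ± 0.16. Zpbp, Acr, Prss37 and Spag6 lie outside the naming rule and were chosen after their values were seen. Both lists had a camera adjusted p = 0.00413 and an adjusted p = 0.124 with an estimated correlation. Their medians under median scaling were -0.28 and -0.19, against 0.30 for all genes. Stress and immediate early genes (15 up and 4 down of 21, median 0.61; adjusted p = 0.00288) included Fos, an immediate early transcription factor, up by 2.34 ± 0.16, and Zfp36, an RNA decay factor, up by 1.91 ± 0.13, with an adjusted p = 0.0544 with an estimated correlation. Antioxidant genes (14 up and 3 down of 26, median 0.34; adjusted p = 0.00333) included the glutathione transferases Gstp1 at 2.90 and Gstm2 at 2.79, with an adjusted p = 0.310 with an estimated correlation. Ribosomal protein genes (27 up and 3 down of 47, median 0.49; adjusted p = 0.00260) included Rpl39 at 2.18 and Rpl22 at 1.70, with an adjusted p = 0.681 with an estimated correlation. The Sertoli markers, with a median of 2.86, rose in the same samples.

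Metabolic genes moved in both directions from round to condensing wild-type samples, and no metabolic list was called. Of 19 glycolysis genes 11 rose and 6 fell (median 0.26, camera adjusted p = 0.189): Pfkl, a phosphofructokinase of widely expressed type, rose by 2.92 ± 0.16 and Gapdh by 1.73 ± 0.10, while Pfkp fell by 1.65 ± 0.16 and Ldha, a lactate dehydrogenase, by a log2 change of -0.80 ± 0.10. Of 65 oxidative phosphorylation genes 21 rose and 12 fell (adjusted p = 0.318), with Cycs, the somatic cytochrome c, up by 2.14 ± 0.11. Of 30 fatty acid oxidation genes 13 rose and 10 fell (adjusted p = 0.678), with the enoyl-CoA hydratase Echs1 at 2.15 ± 0.12 and the electron transfer flavoprotein Etfb at -1.72 ± 0.11. The genes named in these 3 metabolic lists lie outside the naming rule too and were chosen after their values were seen. Counts up and down were 2 and 2 of 7 for glucose and lactate transport (adjusted p = 0.950; camera up and fry down), 4 and 5 of 18 for the citric acid cycle list (0.678), 6 and 2 of 13 for cholesterol synthesis (0.193) and 13 and 12 of 33 for fatty acid and glycerolipid synthesis (0.475). The remaining lists were not called: autophagy (10 up and 8 down of 28; 0.680; median -0.00, mean 0.09), vesicle trafficking (13 and 21 of 46; 0.679; median -0.27, mean 0.01), haploid transcription (3 and 10 of 21; 0.187), sex-linked multicopy genes (4 and 4 of 9; 0.805), acetylation writers, readers and erasers (4 and 16 of 28; 0.0811) and the proteasome (5 and 16 of 33; 0.142). The chromatin packaging list had 7 up and 8 down of 20 (0.855), with a median of -0.13, a mean of 0.14 and a camera direction of up. Medians of the chromatin packaging, vesicle, haploid transcription, autophagy and spermatogonia lists turned positive under median scaling (0.47, 0.06, 0.08, 0.21 and 0.42). Adjusted over the list alone, counts changed by at most 2 genes, the largest being glycerolipid synthesis with 14 down.

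Most stage changes were shared by the genotypes, while some gene lists differed. In the knockdown 3284 genes rose and 3481 fell from round to condensing spermatids. 2836 genes rose in both genotypes (996 by chance) and 3130 fell in both (1178 by chance), 3 fell in wild type and rose in the knockdown, and 0 did the reverse. Log2 stage changes of the genotypes correlated across genes at r = 0.957 (Spearman 0.945), where genes are not independent replicates. Sertoli markers rose in 13 of 14 cases (median 2.76, adjusted p = 6.62e-11 and 0.0318 with an estimated correlation), acrosome genes fell in 20 of 31 and flagellum genes in 27 of 45. Ribosomal protein genes had 37 up and 1 down of 47, and oxidative phosphorylation genes 26 up and 7 down of 65 (camera adjusted p = 0.0358; adjusted p = 0.782 with an estimated correlation), both of which were low on round knockdown replicates 8 and 10. Stress and immediate early genes had 11 up and 5 down of 21 in the knockdown (median 0.44, against 0.61 in wild type), and their camera call was lost (adjusted p = 0.0744, against 0.00288). Endothelial markers had 6 up of 10 (median 0.56, against 1.00; adjusted p = 0.0278, and adjusted p = 0.219 with an estimated correlation), and 13 of 15 leukocyte markers rose (median 1.95-fold, against 2.84-fold; camera adjusted p = 1.53e-04, and adjusted p = 0.165 with an estimated correlation). Of 28 lists camera called 10 in each genotype with the preset correlation, 9 of them in both. Stress genes were the other list called in wild type and oxidative phosphorylation the other in the knockdown, and with the estimated correlation 1 list, the Sertoli markers, was called in each.

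**Figure D3:**
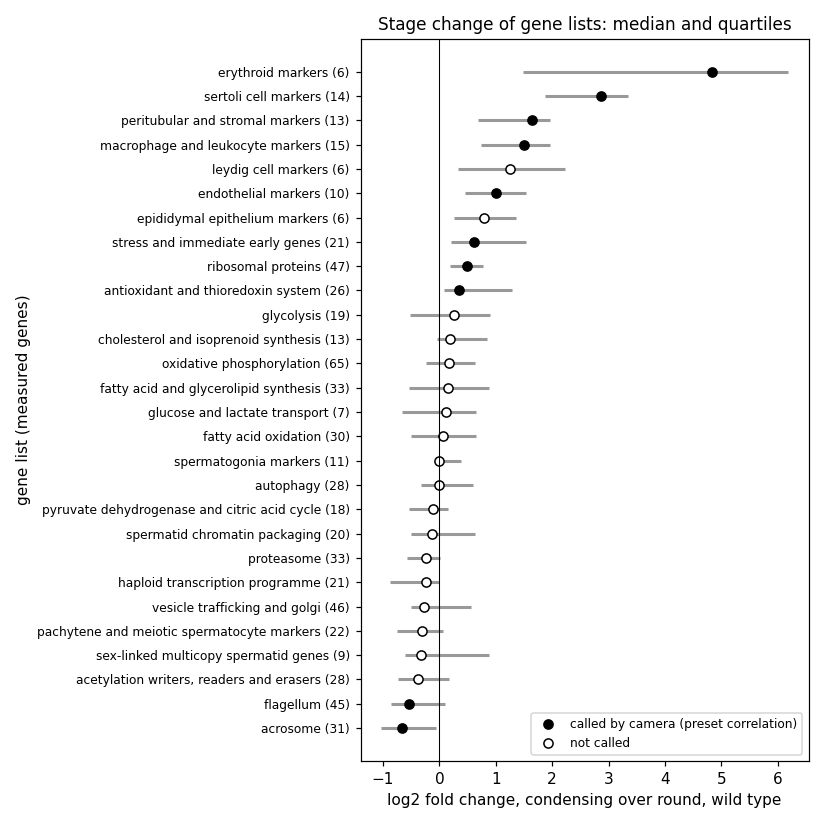
Median log2 change from round to condensing spermatids for each gene list, with quartiles of its members, in wild type. Filled points are lists called by camera with the preset correlation. Sertoli markers have a median of 2.86, and acrosome genes -0.66.

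In round spermatids the comparison asks how knockdown samples differ from wild type before condensation, and no gene passed the test. Of the packaging genes, Tnp2 differed by -0.00 ± 0.15 log2 and Brdt by -0.03 ± 0.12 (SE, n = 6 per group). Tnp1 and Prm1 gave 0.08 ± 0.09 and 0.04 ± 0.10, but they stood at 14.5 and 14.9 log2 in wild type, where quantile normalization sets the highest value of every array at 15.2, so a difference could be hidden. The genes with the smallest p were Trim80 at 0.42, Vwf at 0.42 and Ankrd11, a chromatin regulator, at -0.43, none called. The brightest markers of other cell types differed by 0.49 for Hbb-bs, 0.31 for Aard, 0.13 for Stag3, 0.13 for Insl3, 0.04 for Egfl7, 0.02 for Sohlh1, -0.12 for Dcn, -0.14 for Cuzd1 and -0.15 for Lyz1. Another probe gave 0.12 for Ankrd11 and -0.24 for Insl3, and other Egfl7 probes gave 0.18 and -0.18. The limma test called 0 of 10759 genes, with a smallest adjusted p of 0.894, and 388 genes had an unadjusted p under 0.05, where 538 would by chance. Camera with the preset correlation called 5 lists, Sertoli (median 0.22) and erythroid markers (0.30) up and ribosomal proteins (-0.11), oxidative phosphorylation (-0.11) and proteasome (-0.09) down. Each had an adjusted p = 0.830 with an estimated correlation, and none had a member called, while 1 Sertoli marker passed adjusted over the list alone, as did 1 meiotic marker (lower) and 1 endothelial marker. Round wild-type replicate 3 and knockdown replicates 8 and 10 stood apart from the rest of their groups. Without these 3 arrays the gene count was 0 as well, but the list count dropped from 5 to 2, both up, so that no list was called down. Ribosomal protein genes averaged 10.76, 10.51 and 10.82 on these arrays against at least 10.98 on every other round array, oxidative phosphorylation genes 9.47, 9.28 and 9.57 against at least 9.76, and proteasome genes 9.20, 9.22 and 9.11 against at least 9.42.

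In condensing spermatids the comparison asks what the knockdown changes once condensation is under way. Ccl4 and Fos had the largest falls in the knockdown. Ccl4, a chemokine of activated macrophages, fell by 1.84 ± 0.18 log2 (3.58-fold; SE, n = 6 per group, adjusted p = 5.56e-07) and Fos fell by 1.59 ± 0.16 (3.01-fold, adjusted p = 5.56e-07), each lower in all 6 knockdown arrays than in any wild-type array. Gria1, a glutamate receptor subunit, fell by 1.35 ± 0.17 (adjusted p = 4.91e-05) and Il1b, the cytokine interleukin 1 beta, fell by 1.01 ± 0.14 (adjusted p = 3.18e-04), again with no overlap. The size of these falls depended on the processing. Over 28 other settings Ccl4 ran from -1.96 to -0.82, Fos from -1.71 to -0.90, Gria1 from -1.46 to -0.61 and Il1b from -1.07 to -0.46. The largest rises were Igfbp6, a binding protein of insulin-like growth factors, by 1.11 ± 0.22 (adjusted p = 0.0116), the secreted protease Htra3 by 1.04 ± 0.15 (3.61e-04), Pdgfra, a growth factor receptor of stromal cells, by 0.99 ± 0.20 (0.0168) and the protease Prss35 by 0.94 ± 0.22 (0.0443). Another Pdgfra probe gave 0.14 (adjusted p = 0.861), and other Gria1 probes gave -0.75 (0.0614) and -0.96 (9.05e-04). The limma test called 58 genes, 28 up and 30 down, of which 2 and 4 changed at least 2-fold, and 948 genes had an unadjusted p under 0.05. These tests take the 6 arrays of a group as independent, which the labels do not establish. With consecutive arrays as a random block 22 genes were called, Prss35 and the endothelial marker Flt1 not among them, and with the means of consecutive arrays, 3 per group, 5 were called, all falls: Ccl4, Fos, Gria1, Il1b and the endothelial marker Emcn (highest adjusted p = 0.0154), while Igfbp6, Htra3, Pdgfra and Prss35 had adjusted p = 0.196, 0.0508, 0.305 and 0.305.

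**Figure D4:**
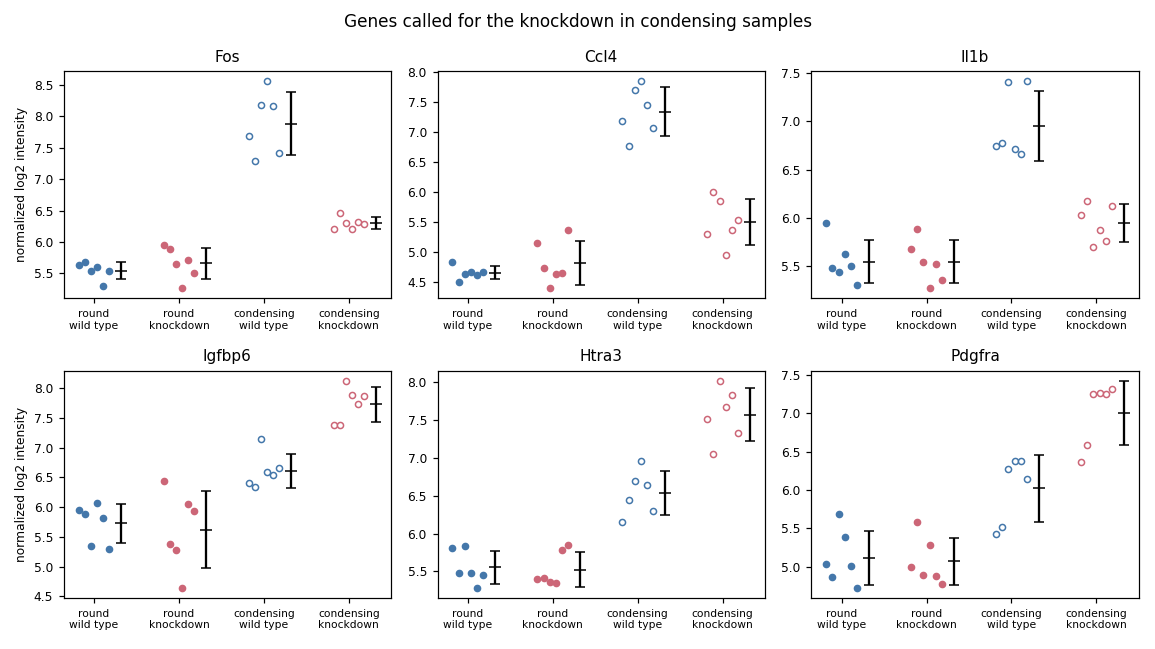
Normalized log2 intensity on each array of Fos, Ccl4, Il1b, Igfbp6, Htra3 and Pdgfra, which were called between knockdown and wild-type condensing spermatids. Gria1, which fell more than Il1b, is not shown. Points are arrays (filled, round; open, condensing; blue, wild type; red, knockdown) and bars are the mean ± SD of 6 arrays; condensing wild-type and knockdown arrays do not overlap for Ccl4 and Fos.

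Of 21 stress and immediate early genes 5 fell in knockdown condensing spermatids and 0 rose: Fos, Zfp36 (-0.88 ± 0.13, adjusted p = 3.61e-04), the transcription factors Egr1 (-0.85) and Junb (-0.69), and the phosphatase Dusp1 (-0.60). Adjusted over the list alone 5 fell and 1 rose; the median was -0.08 and the mean -0.23, and camera gave an adjusted p = 1.62e-04, and adjusted p = 0.0195 with an estimated correlation. Of 10 endothelial markers 3 fell and 0 rose (median -0.25): Emcn, endomucin, at -0.78 ± 0.11 (adjusted p = 1.53e-04), Flt1, a VEGF receptor, at -0.55 ± 0.12 (0.0394) and Esam, an adhesion molecule, at -0.54. Adjusted over the list alone 4 fell, and camera gave an adjusted p = 5.98e-07, and adjusted p = 0.00818 with an estimated correlation. Of 15 macrophage and leukocyte markers Cd14, a receptor for lipopolysaccharide, fell by 0.64 ± 0.14 and 14 were not called (median -0.19; camera adjusted p = 0.00764, and adjusted p = 0.440 with an estimated correlation). None of 14 Sertoli markers was called (median 0.19; adjusted p = 0.00713, and adjusted p = 0.440 with an estimated correlation). Of 13 stromal markers Pdgfra rose and Acta2, smooth muscle actin, fell by 0.75 ± 0.16 (list adjusted p = 0.190; 2 up and 1 down adjusted over the list alone). Adjusted over the list alone, 2 epididymal markers were lower and 1 meiotic marker higher, where none was called over all genes. Egr1, Junb, Dusp1, Esam, Cd14 and Acta2 were named after their values were seen. With the means of consecutive arrays Zfp36 and Flt1 had adjusted p = 0.116 and 0.320, and the number of lists called by camera with the preset correlation stayed at 4. Emcn was detected on 6 of 6 wild-type and 1 of 6 knockdown condensing arrays. Over 27 other settings Emcn ran from -0.85 to -0.24 and Flt1 from -0.62 to -0.17, so the size of both falls depended on the processing.

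No member of a metabolic or spermatid list was called in knockdown condensing spermatids. Median differences were 0.03 for glycolysis (19 genes), 0.09 for oxidative phosphorylation (65), 0.06 for fatty acid oxidation (30), 0.05 for the citric acid cycle list (18), -0.01 for cholesterol synthesis (13), -0.03 for the acrosome (31), -0.00 for the flagellum (45) and 0.06 for chromatin packaging (20). The signs for glycolysis and chromatin packaging turned under median scaling, as did those of glucose and lactate transport, antioxidant, autophagy and ribosomal genes. Tnp2 differed by -0.02 ± 0.15 and Brdt by -0.11 ± 0.12, and Prm1 and Tnp1, again near the top of the scale, by 0.05 ± 0.10 and -0.02 ± 0.09, none called. The brightest markers of other cell types gave 0.60 for Dcn, 0.31 for Wfdc10, 0.30 for Defb19, 0.25 for Hbb-bs, 0.17 for H2-Ab1, 0.04 for Syce3, 0.03 for Uchl1, -0.07 for Insl3 and -0.14 for Egfl7, none called. By count, 20 of the 28 genes that rose and 21 of the 30 that fell were also higher in condensing than in round wild-type spermatids, against 8.49 and 9.10 by chance (Fisher's exact test, one-sided, p = 8.62e-06 and 8.49e-06). The shared wild-type condensing arrays favour genes that fall in the knockdown and rise with stage, which this chance count leaves out. It also takes genes as independent and as equally able to be called whatever their level in condensing samples, so the p-values are too small to be taken as exact. Against the stage change in knockdown, whose shared arrays favour the rises, 25 of 28 and 16 of 30 were higher in condensing spermatids (8.55 and 9.16 by chance; Fisher's exact test, p = 1.43e-10 and 0.00758). With separate sets of 3 wild-type condensing arrays for each contrast, a mean of 3.85 of 5.5 rises and 8 of 9.4 falls were higher in condensing spermatids. For the knockdown effect in condensing spermatids, the count of 58 was 21 under median scaling, 26 with the condensing arrays alone and 105 without the 3 round arrays that stand apart, and it lay between 25 and 48 when a condensing array was left out. Flt1 and Prss35 lost their calls in 10 and 9 of 12 such omissions and Pdgfra in 2, without wild-type replicate 13 and without knockdown replicate 22.

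The test of the difference between the knockdown effects asks whether condensing and round spermatids respond unequally. It called 5 genes, each with a more negative measured difference in condensing spermatids: Ccl4 (-2.01 ± 0.25, SE, n = 6 per group, adjusted p = 1.49e-04), Fos (-1.70 ± 0.23, 1.63e-04), Gria1 (-1.33 ± 0.24, 0.0259), Prf1, the pore-forming protein perforin (-1.13 ± 0.21, 0.0273), and Zfp36 (-0.97 ± 0.18, 0.0291), the last named after its value was seen. In round spermatids the effects were 0.17 for Ccl4, 0.12 for Fos, -0.02 for Gria1, 0.42 for Prf1 and 0.09 for Zfp36, none called, and Ccl4 was detected on 0 of 6 wild-type and 2 of 6 knockdown round arrays, so that a fall of Ccl4 could not have appeared in round spermatids. Fos, Gria1 and Zfp36 were detected on 6 of 6 wild-type round arrays, with means of 5.54, 5.38 and 5.49 there and of 7.88, 7.11 and 7.39 in wild-type condensing spermatids. On knockdown round arrays Fos and Zfp36 were detected on 6 of 6 and Gria1 on 4 of 6, with means of 5.66, 5.57 and 5.36. Ccl4, not detected there, averaged 4.65 on wild-type round arrays. Falls of Fos, Gria1 and Zfp36 in round spermatids would therefore have been compressed by background, and how much of them could have appeared was not tested. A total of 747 genes had an unadjusted p under 0.05. Camera called 6 lists with the preset correlation. Endothelial markers (median -0.31; adjusted p = 7.22e-05) and stress and immediate early genes (median -0.10; adjusted p = 1.03e-04) each had an adjusted p = 0.0211 with an estimated correlation; 0 of 10 and 2 of 21 members were called, and 3 and 5 were lower adjusted over the list alone. Oxidative phosphorylation (0.20), proteasome (0.16), ribosomal (0.17) and leukocyte lists (-0.23) had adjusted p = 0.898, 0.569, 0.898 and 0.569 with an estimated correlation, and the former 3 were low on round wild-type replicate 3 and round knockdown replicates 8 and 10. Gria1 and Prf1 lost their calls in 6 and 8 of 24 omissions of an array, and with consecutive arrays as a random block or as means 2 genes, Ccl4 and Fos, were called.

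Knockdown effects in round and condensing spermatids showed no positive relation. Their log2 differences correlated at r = -0.09 (Spearman -0.09, jackknife error 0.10, across 10759 genes that are not independent replicates), and with 0 genes called in round spermatids no overlap of calls could arise. The knockdown effect in condensing spermatids against the wild-type stage change gave r = -0.00 (Spearman -0.03). Shared wild-type condensing arrays alone gave r = -0.08 ± 0.13 (SD) in simulations without a knockdown effect. With these arrays divided into sets of 3, a separate set for each contrast, the mean r over 20 splits was 0.06 (range -0.02 to 0.18).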

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

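The test on detected probes, the comparison of the 3 round arrays over 28 lists, the splits and means of consecutive arrays and the covariate for residual variation were chosen after the data were seen. The other tests named here were set beforehand. For the stress response to cell preparation, the allowance for the members' spread was not part of the bound set beforehand. That bound alone counted against this cause. In 172 sets of 6 arrays, from 53 named genes and 9 marker lists, 11 had an array farther from the rest than Dixon's 95% criterion allows, where chance gives about 1 in 20, here 8.6. Round wild-type replicate 3 held 4 of these: Cd74 at 6.22 log2 (next array 6.70), Cst12 at 6.18 (6.66), Cryba2 at 8.25 (7.78) and Ep300 at 8.67 (7.90). In wild-type condensing samples, Fcer1g reached 7.40 in replicate 15 (7.09), and replicate 18 had Syce3 at 12.97 (12.8) and Xntrpc at 5.39 (6.10). In knockdown condensing samples, Zfp36 was 6.81 in replicate 21 (6.52), the Leydig marker mean 7.36 in replicate 20 (7.17) and the spermatogonia marker mean 6.53 in replicate 19 (6.30). The leukocyte marker mean was 5.92 in round knockdown replicate 10 (6.20).

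The difference between the knockdown effects in condensing and round spermatids passed its test for Ccl4 (-2.01), Fos (-1.70), Gria1 (-1.33), Prf1 (-1.13) and Zfp36 (-0.97). Ccl4 was not detected on any round wild-type array, so its value does not show an effect that depends on the stage. Fos, Gria1 and Zfp36 were detected but low there (5.54, 5.38 and 5.49), so falls would have been compressed. How far their values show an effect that depends on the stage stays open. Of 100 splits of the arrays 3 gave 5 or more such genes, the real split included, but of 100 splits that keep consecutive arrays together 20 did (highest other 1167), so chance is excluded only if consecutive arrays are independent. The count of 5 is not stable, however: it ran from 2 to 19 when an array was left out and was 74 with a covariate for residual variation, and a simulation with no effect gave up to 3. The highest of the other splits called 1114 genes, which points to a structure of the samples.

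Sertoli and erythroid genes were among the largest rises from round to condensing wild-type samples, and 1 of 100 splits gave as many stage calls (6903, highest other 4608 for a split that put 5 round and 1 condensing array together), so chance can be excluded for independent arrays, as it can in the knockdown (1 of 100; 6765, highest other 4598). The 10 splits that keep consecutive arrays together are too few for a share under 0.05, with a highest other count of 0 in both genotypes (1 of 10 as large). A lower share of germ cells that raises every other cell type alike did not meet the bound set beforehand. The medians of the Sertoli, Leydig, leukocyte, stromal and endothelial markers lay up to 1.87 log2 apart, with quartiles of 1.88 to 3.34 for Sertoli and 0.46 to 1.54 for endothelial markers. But endothelial markers averaged only 5.66 log2 in round wild-type samples (Sertoli markers 6.59), and folds near background are compressed towards 1. So the gap does not exclude that cause. Erythroid markers, which this comparison left out, averaged 6.55 log2 in round wild-type samples and rose by a median of 4.84. Their quartiles (1.48 to 6.18) overlap those of the Sertoli markers. Normalization between arrays is argued against, because the Sertoli median was at least 1.62 under the 3 other scalings. Cells or cell fragments of another type in the condensing fraction are a candidate explanation: the 11 Sertoli markers not looked at beforehand had a median of 2.25 (quartiles 1.77 to 3.25), and mean levels in wild-type condensing samples reached 14.3 for Hbb-bs, 10.9 for Cldn11 and 10.6 for Cst12, the latter genes being detected on all 6 round wild-type arrays too. Transcription of such genes by spermatids themselves, a difference the stage labels would name, stays open as untested.

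Fos, Egr1, Junb, Zfp36 and Dusp1 of the immediate early list, and Ccl4 and Il1b outside it, fell in knockdown condensing samples, among 58 calls for which chance can be excluded if the 12 arrays are independent (1 of 100 splits, highest other 3); the splits do not test these genes as a group. The 10 splits that keep consecutive arrays together are too few for a share under 0.05 (1 of 10 as large, highest other 3), and with the means of consecutive arrays 5 genes were called, Ccl4, Fos, Gria1, Il1b and Emcn. A single array is argued against for Fos, which was called in 12 of 12 omissions (-1.46 to -1.71, highest limma adjusted p 4.73e-06). Ccl4, Il1b and Zfp36 also kept their calls in all 12 (highest adjusted p 4.73e-06, 0.00193 and 0.00223). Omissions were not examined for Egr1, Junb and Dusp1. Fewer macrophages in the knockdown samples remains open, with a leukocyte marker median of -0.19 (quartiles -0.35 to 0.01), and so does a stress response to cell preparation that differed between the genotypes' samples, with a list median of -0.0785 above the bound set beforehand by less than the members' spread (quartiles -0.34 to -0.01; 16 below 0, 5 above). A change in the amount or state of cells other than spermatids in the condensing fraction may underlie many of the 58 calls: their stage change averaged over genotypes had a median of 0.88 (quartiles 0.30 to 1.39), 46 lay above 0, and the median of all genes was -0.01. An effect of the knockdown within spermatids, which the design names, also stays open, and the arrays alone do not separate these.

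Round wild-type replicate 3 and round knockdown replicates 8 and 10 stood apart within their groups, on an axis that held 34.7% of the variance left within groups. More meiotic cells in those arrays stays open. The meiotic marker mean was 8.90, 8.76 and 8.85, in 3 of 3 above all other round arrays (8.50 to 8.67), which met the bound set beforehand for this cause. Of 28 lists 6 lay above and 7 below all other round arrays there. Haploid transcription (10.70, 10.77 and 10.68 against at most 10.54) and flagellum genes lay above, and acrosome, ribosomal and oxidative phosphorylation genes below. How far meiotic cells express the genes of these lists was not measured here, so these lists do not decide the question. More detected probes on those arrays stays open too, because 2 of 3 (18411 and 18325, with 17871 for knockdown replicate 8) exceeded the highest other array (18142). For the knockdown effect in round spermatids a real count of 0 is reached by 100 of 100 splits, and by 10 of 10 that keep consecutive arrays together (highest other 2520), whatever the data, so the splits say nothing about chance there, and the highest other split called 2608 genes with wild-type replicates 1, 2 and 4 and knockdown replicates 9, 11 and 12 on a side, which points to this structure of the samples. The labels name no biological difference between these arrays and the rest, so none from the design was tested.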

How the results depend on the processing

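The omission of the 3 round arrays together, the covariate for residual variation and the 3 treatments of consecutive arrays were chosen after the data were seen. Outside single-array omissions, 117 counts stayed within 1.5 times their value and 33 did not, 1084 values of named genes kept direction and side of the threshold, 32 lost and 3 gained a call, 18 changed sign without a call in either setting, and 22 correlations were the same. Under median scaling Tnp1 and Prm1 turned to 0.90 and 0.61 in the stage change in wild type, and of the uncalled values Brdt turned to 0.14 there and Prm1 and Syce3 to -0.10 and -0.05 in the knockdown effect in condensing spermatids. Among single omissions 41 uncalled values changed sign. The cause of the moves below was not tested, except where fewer arrays, a stricter threshold or another correlation makes them by construction.

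For the knockdown effect in condensing spermatids (58 genes), counts were 21 with median scaling, 25 with quantiles within each cell type, 26 with the contrast's own arrays, 116 with array weights, 12 at an adjusted p under 0.01, 37 at a fold change of at least 1.5, 105 without the 3 round arrays, 135 with the covariate, 22 with consecutive arrays as a random block, 5 with their means and 81 with their position as a fixed block. Single omissions gave 25 to 48: 33, 27, 27, 31 and 35 without wild-type replicates 13, 15, 16, 17 and 18, and 32, 25 and 37 without knockdown replicates 21, 22 and 24. For the knockdown effect in round spermatids (0 genes), all detected probes gave 1, the covariate 6, and omissions 0 to 1 (1 without knockdown replicate 11). For the difference between the knockdown effects (5 genes), counts were 2 with median scaling, 11 with no and 13 with a stricter detection filter, 8 with the mean of a gene's probes, 16 with array weights, 2 at an adjusted p under 0.01, 74 with the covariate, 2 with consecutive arrays as a random block, 2 with their means and 16 with their position as a fixed block. Omissions gave 2 to 19: 19 without round wild-type replicate 3, 2 without 4, 5 or 6, 3 without round knockdown 7, 8 or 11, 9 without condensing wild-type 14, 3 without 15 or 16, 11 without condensing knockdown 20 and 3 without 24. The stage change in wild type gave 4537 genes and the stage change in knockdown 4502 at a fold change of at least 1.5, with omissions at 6640 to 6798 and 6568 to 6754.

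List counts with an estimated correlation were 0, 2, 1, 1 and 2 (round and condensing knockdown effects, stage change in wild type and knockdown, difference) against 5, 4, 10, 10 and 6. The condensing count was 7 with the contrast's own arrays. The round count was 2 with array weights, 3 at an adjusted p under 0.01 and 2 without the 3 arrays, and omissions gave 2 to 5: 3, 2 and 3 without wild-type replicates 1, 2 and 3, and 2, 3 and 3 without knockdown replicates 8, 10 and 11.

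Some named genes sat near the threshold. Without an array Flt1 was called only when condensing wild-type 18 or knockdown 19 was omitted (-0.62 to -0.47, adjusted p up to 0.113), Prss35 only without wild-type 16 or knockdown 19 or 20 (0.79 to 1.04, up to 0.143), and Pdgfra in all omissions but those of wild-type 13 and knockdown 22 (0.87 to 1.12, up to 0.0557). Prm1 in the stage change in wild type was called only without round 4 or 6 or condensing 13 or 14 (-0.26 to -0.19, up to 0.0937). In the difference between the knockdown effects Gria1 lost its call without round wild-type 4, 5 or 6, round knockdown 7 or 8 or condensing wild-type 16 (-1.43 to -1.20, up to 0.0636), and Prf1 without round wild-type 4, 5 or 6, round knockdown 11, condensing wild-type 15 or 16 or condensing knockdown 21 or 24 (-1.22 to -1.05, up to 0.0651). Brdt gained a call in the stage change in wild type with the mean of a gene's probes (-0.60) and with the contrast's own arrays (-0.24), and Trim80 in round spermatids with the covariate (0.42).

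No pairing of samples between groups could be taken from the labels, because replicate numbers run from 1 to 24 and none is shared between groups. A pairing of consecutive arrays within a group (13 with 14, and so on) comes from the data, not the labels, and the evidence for it is mixed. The correlation of deviations from the group mean was over 0.1 in 2 of 12 pairs, with a mean of -0.02 within and -0.23 between pairs, and the consensus correlation was 0.15. Deviations of independent arrays from their own group mean correlate negatively on average. The mean of -0.02 within pairs therefore does not count against the pairing. More variance between than within pairs was called for 181 genes, a count reached by 2 of 100 pairings, the real one included (highest other 1225). A position effect shared by both genotypes was called for 9 genes in condensing samples (1 of 100 arrangements, highest other 1) and for 0 in round samples. So the arrays of a group are not shown to be independent. A fit with slides as a block was not run because no slides are named in the files. Signal over background limits the fold of probes not detected in a group, which is compressed towards 1.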

Other observations

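Several genes outside the fixed lists rose in knockdown condensing spermatids beside Igfbp6 and Htra3; they were picked after their values were seen, and no list of them was tested. Col6a1, a collagen chain, rose by 0.83 ± 0.14 log2 (SE, n = 6 per group, limma adjusted p = 0.00350), Hspg2, the basement membrane proteoglycan perlecan, by 0.67 ± 0.11 (0.00342), Ccn5 by 0.69 ± 0.13 (0.00855) and Nid1, a basement membrane linker, by 0.56 ± 0.13 (0.0482). Cd34, a surface protein of vascular and stromal progenitors, rose by 0.66 ± 0.15 (0.0439), while Mmrn2, a matrix protein of endothelium, fell by 0.47 ± 0.11 (0.0492). Of the genes that fell, Ccl21a, a lymphoid chemokine gene, fell by 0.91 ± 0.17 and Cebpa, a myeloid transcription factor, by a log2 change of -0.59 ± 0.13 (0.0358). With the means of consecutive arrays, where 5 genes were called, none of these was. In the same samples the stromal marker median was 0.15 and the endothelial marker median -0.25.

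Pdgfra values in condensing samples were 5.43 and 5.52 in wild-type replicates 13 and 14 and 6.14 to 6.38 in the other 4, and 6.37 and 6.59 in knockdown replicates 19 and 20 and 7.25 to 7.32 in the other 4. Dcn values were 10.30 and 10.27, 10.84 and 10.79, and 10.59 and 10.26 in wild-type replicates 13 to 18, and 10.69 and 10.75, 11.49 and 11.48, and 11.17 and 11.06 in knockdown replicates 19 to 24. Both genes were picked after their values were seen. Dates and slides of the arrays are not given in the sources used here.

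A delayed transition in the knockdown was tested as a hypothesis, since condensing knockdown samples that lag towards round spermatids would have a knockdown effect opposite to the stage change. With separate wild-type condensing arrays for each contrast, the mean correlation across genes over 20 splits was 0.0570, with a jackknife error of that mean of 0.0889 and a range of -0.00 to 0.10 when an array was left out. The mean did not have the sign a delay predicts, and under the rule set beforehand a mean over 0 counted against a delay. That rule left out the error. It also left out that markers of other cell types rise with stage. Their median knockdown effects in condensing samples were 0.19 for Sertoli, 0.20 for erythroid, 0.15 for stromal, -0.19 for leukocyte and -0.25 for endothelial markers. The part of such genes in the correlation was not removed, so it could hide or mimic a delay. The mean lay within its error of 0, so a small delay stays open.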
